A study of Mus musculus with 6 samples.

How the data were processed

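Total RNA of the stria vascularis of the mouse cochlea at postnatal day 10 was extracted with a Qiagen kit and amplified and labelled with the NuGEN Ovation protocol, per the labels' protocols. It was hybridised to Affymetrix Mouse 430 2.0 arrays, on which a gene is measured by 1 or more probe sets, each a group of short probes near the 3' end of the transcript. The deposited values are signal intensity on a linear scale, made with the array maker's software GCOS per the submitters' processing notes, with a version not given in the sources used here. The table held 45101 probe sets on 6 arrays, and none of its values was at or below 0. Each array's mean after trimming 2% at either end was 500.002, so the arrays had been scaled to a common level before deposit. No aligner or genome build applies, and no coordinates are given.

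Genotype and replicate number were taken from the sample titles, with 3 heterozygous and 3 knockout arrays. The comparisons, tests, gene lists, rule for named genes and alternatives, except those said to be added, were fixed before the data were examined. The 64 control probe sets were left out of the tests. The signal was transformed as log2(signal + 16), and fold changes are on this scale, which understates the change of dim genes. Probe sets whose mean over all arrays lay under the 40th percentile, a signal of about 43.9, were removed, which left 27022. The values were kept as scaled at deposit, since the trimmed means were equal. Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Signals are given as mean ± SD, and ± beside a log2 difference is marked as SE.

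Probe sets were named from the array platform's annotation. Of 45037 probe sets that are not controls, 34945 had 1 gene symbol, 932 several and 9160 none, and a probe set without a symbol is unnamed here. By gene identifier, 34741 of the named ones were matched to a RefSeq gene table of assembly GRCm38.p6 and 204 were not, and no symbol was changed. For each of 12428 genes, the brightest tested probe set over all arrays stood for the gene. The RefSeq table was otherwise used only to find which genes neighbour Slc26a4.

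Gene lists were cell type markers (strial intermediate, marginal and basal cells, root, spindle and outer sulcus cells, macrophages, lymphocytes, granulocytes, erythrocytes, endothelial cells, pericytes, fibrocytes, cartilage and bone, hair cells, neurons, Schwann cells and skeletal muscle) and pathway lists (oxidative stress, acid-base transport, calcium transport, thyroid hormone, chloride and strial channels, tight junctions, complement, antigen presentation, interferon response, cytokines, lysosome, unfolded protein response, immediate early genes, proliferation, glycolysis, oxidative phosphorylation, extracellular matrix, melanin and metal handling). Lists with at least 3 tested members, 33 in number, were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The skeletal muscle list had 0 tested members. For each list, members were also adjusted over the list alone, with no adjustment across lists. The text names Slc26a4, up to 8 genes per direction by p where fewer were called, up to 2 members of each list with the smallest p, and a fixed set of strial, stress and sex-linked genes. Other list members were named after their values were seen.

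The single-gene test was checked on data simulated from the fitted means and spreads over 27022 probe sets. It recovered 42 of 100 planted 2-fold changes and 98 of 100 planted 4-fold changes, with 8 false calls. The simulated noise was independent and had the same spread on all arrays, and many changes were planted at once, which eases the adjustment. The real arrays include an outlying one and gave few calls, so these shares need not hold for them. Tex35, with a log2 difference of -2.08, was not called (limma adjusted p = 0.0541). In 50 simulations over 12428 genes, camera called a list planted with a log2 shift of 0.8 each time, and 26 of 1550 tests of unchanged lists, with genes drawn independently of each other.

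Alternatives were other offsets (1 and 64), a floor of 32, quantile and cyclic loess normalisation, median centring, no filter or a 60th percentile filter, no variance trend, robust variance, array weights, other thresholds, an unmoderated test, other ways to sum up probe sets, windows of 5 and 20 Mb around Slc26a4, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.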

Results

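RNA of the stria vascularis, the vascularised epithelium of the lateral wall of the cochlea that secretes potassium into the endolymph, was measured on 6 oligonucleotide arrays from mice at postnatal day 10. The mice carried either 1 or no working copy of Slc26a4, which encodes pendrin, an anion exchanger of the inner ear, thyroid and kidney whose loss causes deafness. There were 3 arrays of heterozygous mice (replicates 1, 3 and 5) and 3 of knockout mice (replicates 2, 4 and 6). The comparison asked how gene expression in this tissue differed between the genotypes before the age at which hearing starts. The number of arrays limits the precision of every value. The labels do not say whether arrays came from separate animals or from pools, so p-values measure the spread between these samples, in which animal and technical spread were not separated.

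The targeted gene was lower in the knockout samples. Slc26a4 gave a signal of 491.6 ± 445.6 (SD, n = 3) in heterozygous samples and 111.6 ± 39.4 (SD, n = 3) in knockout samples, on its only probe set on the array. The heterozygous values were 220.8, 248.2 and 1006, and the knockout values were 75.5, 106 and 154, so each knockout sample lay below each heterozygous one. The log2 difference was -1.69 with a standard error of 0.50, and its limma adjusted p of 0.370 did not pass the threshold of 0.05. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 samples allow. The sources used here do not give the place of this probe set relative to the deleted part of the gene, so its remaining signal cannot be assigned to a transcript. Without heterozygous replicate 5, the highest value, the log2 difference was -1.02. Other genes were also highest in that array, with heterozygous signals in replicates 1, 3 and 5 of 42.7, 102 and 772 for Aqp4, 27.8, 65.4 and 350 for Otog, and 4332, 6598 and 10405 for Epyc. The list of root, spindle and outer sulcus cells had its highest median deviation from the heterozygous mean there as well (0.46), so the size of the Slc26a4 difference was not separated from the cell content of that sample.

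**Figure D1:**
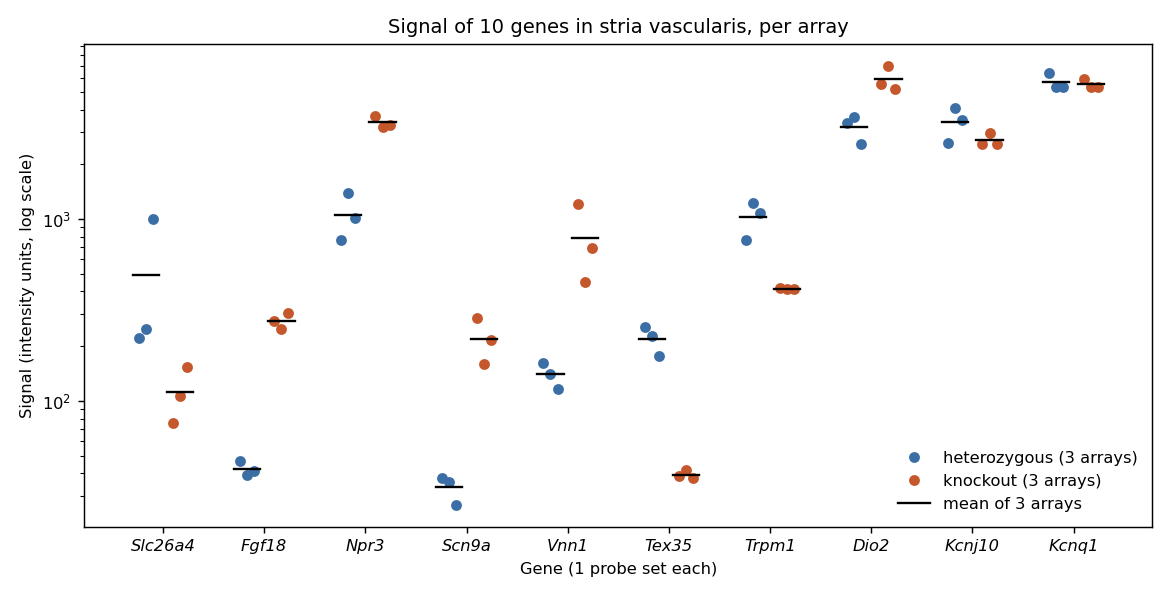
Signal of 10 genes on a logarithmic axis in intensity units, with 1 point per array, heterozygous in blue and knockout in orange, and black bars for the mean of the 3 arrays. Fgf18 sat between 38.9 and 46.7 in heterozygous samples and between 249 and 304 in knockout samples, whereas Kcnq1 overlapped between the genotypes.

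Across the genome, 1 gene passed the threshold. Fgf18, a fibroblast growth factor that acts in skeletal development, rose from 42.3 ± 4.0 to 276 ± 27.5 (SD, n = 3 each), a 5.0-fold increase on the offset scale (log2 difference 2.32, standard error 0.22, limma adjusted p = 0.0326), and was higher in 3 of 3 knockout samples. The call was kept without knockout replicate 4 (adjusted p = 0.0133). Leaving out any other array ended it, with an adjusted p between 0.0845 and 0.348 with a log2 difference between 2.25 and 2.38. Over all alternatives the limma adjusted p ranged from 0.00239 to 0.348 and the log2 difference from 1.68 to 2.71. The heterozygous mean of Fgf18, 5.86 on the log2 scale, lay under the filter cutoff of 5.90. Its heterozygous level was thus near background, and the gene passed the filter through its knockout values. Of the 27022 probe sets tested, 1 was called, and 5 had an adjusted p under 0.1. At an unadjusted p under 0.05 there were 3138 probe sets, against 1351 that chance alone would give, of which 2471 were higher and 667 lower in knockout samples. Unnamed probe sets made up 1221 of those higher and 53 of those lower. Of the unnamed ones tested 34.6% were higher at that p, against 5.3% of the named ones, a shift taken up under the other observations. Quantile normalisation gave 1750 higher and 966 lower. Without heterozygous replicate 3 there were 1143 higher and 292 lower, without heterozygous replicate 5 1430 and 289, and without knockout replicate 6 3702 and 1523, so the excess over chance varied with single arrays. Counted by gene, 789 of 12428 had an unadjusted p under 0.05, against 621 by chance, with 391 higher and 398 lower. The groups did not overlap for 13.1% of genes, where chance gives 10%.

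Several genes followed Fgf18 in rank without passing the threshold, and they are given as values. Among those higher in knockout samples, Npr3, the clearance receptor for natriuretic peptides, had a log2 difference of 1.71 ± 0.19 (SE, adjusted p = 0.0541), with 1058 ± 310 in heterozygous and 3408 ± 261 in knockout samples (SD, n = 3 each). Scn9a and Scn7a, a voltage-gated sodium channel and its sodium-sensing relative, had log2 differences of 2.23 and 1.64 (limma adjusted p = 0.0676 and 0.113). Vnn1, a pantetheinase that forms the antioxidant precursor cysteamine, stood at 140 ± 23.3 in heterozygous and 785 ± 389 in knockout samples (SD, n = 3 each), a log2 difference of 2.26 (limma adjusted p = 0.113), and its other probe set gave 2.32. Gask1b, a secreted Golgi protein, differed by 2.06, Itih3, a hyaluronan-binding inter-alpha-trypsin inhibitor chain, by 1.47, and the matrix protein Thbs1 by 1.497. In all 8 of these genes, Fgf18 included, every knockout sample lay above every heterozygous sample.

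In the other direction, Tex35 had the lowest adjusted p (log2 difference -2.08 ± 0.23 SE, limma adjusted p = 0.0541), with a signal of 220 ± 39.1 in heterozygous and 39.3 ± 2.02 in knockout samples (SD, n = 3 each). Trpm1, a cation channel of melanocytes, stood at 1025 ± 232 in heterozygous samples and at 414 ± 3.30 in knockout samples (SD, n = 3 each), a log2 difference of -1.25 (limma adjusted p = 0.157), and its other probe sets gave -1.61 and -1.57. Gpr176, an orphan G protein-coupled receptor, differed by -1.04, and Aldh1a2, which makes retinoic acid, by -0.72. The values were -1.79 for Rerg, a growth inhibitor of the Ras family, and -1.55 for Kcnab1, a potassium channel beta subunit. They were -1.72 for AA467197 and -0.88 for Gchfr, the feedback regulator of tetrahydrobiopterin synthesis. None of these 8 genes passed the threshold, and the groups did not overlap in any of them.

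Knockout replicate 4 stood apart from the other arrays, and it moved how many genes were called. Without it, 13 probe sets passed, 11 higher and 2 lower, which stood for 10 named genes and 1 unnamed probe set. The named genes were Fgf18, Vnn1, Scn9a, Npr3, Gask1b, Itih3, Klhdc8a, Pdlim1 and Prss35, all higher, and Tex35, lower. In the array left out, Prss35 lay at 61.5, below each heterozygous sample (82.6, 97.2 and 102). With all samples its limma adjusted p was 0.519. Klhdc8a, Pdlim1 and Prss35 fall outside the rule for named genes and were chosen after their values were seen. Fitting only 1 probe set per gene, an alternative also chosen after seeing the data, called 11 genes, 7 higher and 4 lower. These were Fgf18, Npr3, Scn9a, Gask1b, Itih3, Scn7a and Vnn1 above, and Tex35, Gpr176, Rerg and Aldh1a2 below.

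No marker of the cells of the stria passed over all probe sets. Kcnq1 and Kcne1, the subunits of the potassium channel of marginal cells, had log2 differences of -0.04 ± 0.10 and -0.03 ± 0.11 (SE), and Slc12a2, their sodium-potassium-chloride cotransporter, 0.18 ± 0.09. Kcnj10, the potassium channel of intermediate cells, stood at 3402 ± 728 in heterozygous and 2717 ± 213 in knockout samples (SD, n = 3 each), a log2 difference of -0.30 ± 0.16 SE that did not pass the test (limma adjusted p = 0.486). Its log2 difference was -0.16 without heterozygous replicate 3 and -0.47 without heterozygous replicate 1. Tyr, the melanin-forming tyrosinase, gave -0.02 ± 0.11, Cldn11, the tight junction protein of basal cells, 0.05 ± 0.08, and Gjb2, a gap junction protein, 0.19 ± 0.09. Without knockout replicate 4, Slc12a2 gave 0.08, Gjb2 0.09, Kcne1 -0.14 and Tyr 0.10. Other probe sets lay on the opposite side for Slc12a2 (-0.02) and Tyr (0.09), and over all alternatives the sign turned for Kcnq1, Kcne1, Tyr and Cldn11, between -0.14 and 0.12. The medians of the cell lists were -0.03 for 9 marginal cell genes, -0.00091 for 7 basal cell genes and -0.11 for 15 intermediate cell and melanocyte genes. In the last list 12 members were lower and 3 higher, and Trpm1 passed when adjusted over the list alone (adjusted p = 0.00139). That list did not pass with all samples (adjusted p = 0.105), but it did in 4 of 20 alternatives, among them without heterozygous replicate 1 (adjusted p = 0.00651), with an adjusted p from 0.00651 to 0.812. The medians of the marginal and basal cell lists turned in sign under some alternatives, between -0.10 and 0.06. Kcnj13 had -0.66 in that list, and Bsnd, a chloride channel subunit of marginal cells, -0.47. For 4 root, spindle and outer sulcus cell genes, the cells in which pendrin is made, the median was -0.57, with Epyc at -0.996 and Anxa1 at 0.20. That median was -0.23 without heterozygous replicate 5 and -0.24 without knockout replicate 2. Over all alternatives the log2 difference of Epyc ranged from -1.52 to -0.55.

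Genes of cartilage and bone were higher in knockout samples as a group. Of 10 tested members 9 were higher, with a median log2 difference of 0.97, and the list rose in the camera test with a preset correlation (adjusted p = 8.17e-10). With an estimated correlation the adjusted p = 0.190, so the call was not kept, and over all alternatives the adjusted p ranged from 5.32e-13 to 0.302. No member passed over all probe sets, and 7 passed when adjusted over the list alone, all of them higher. Mmp9, a matrix metalloproteinase of osteoclasts, stood at 32.9 ± 23.4 in heterozygous and 249 ± 229 in knockout samples (SD, n = 3 each), a log2 difference of 2.19. Dmp1, an osteocyte phosphoprotein, stood at 2185 ± 960 and 4571 ± 1136, a log2 difference of 1.11. The others were Phex at 1.62, Acp5 at 1.37, Ibsp at 1.34, Ctsk at 0.82 and Col2a1 at 0.39. Acp5 and Ctsk are also osteoclast enzymes, while Ibsp and Phex belong to mineralising cells and Col2a1 to cartilage. Alpl was the member on the other side (-0.11). The median was 1.06 without knockout replicate 4.

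**Figure D2:**
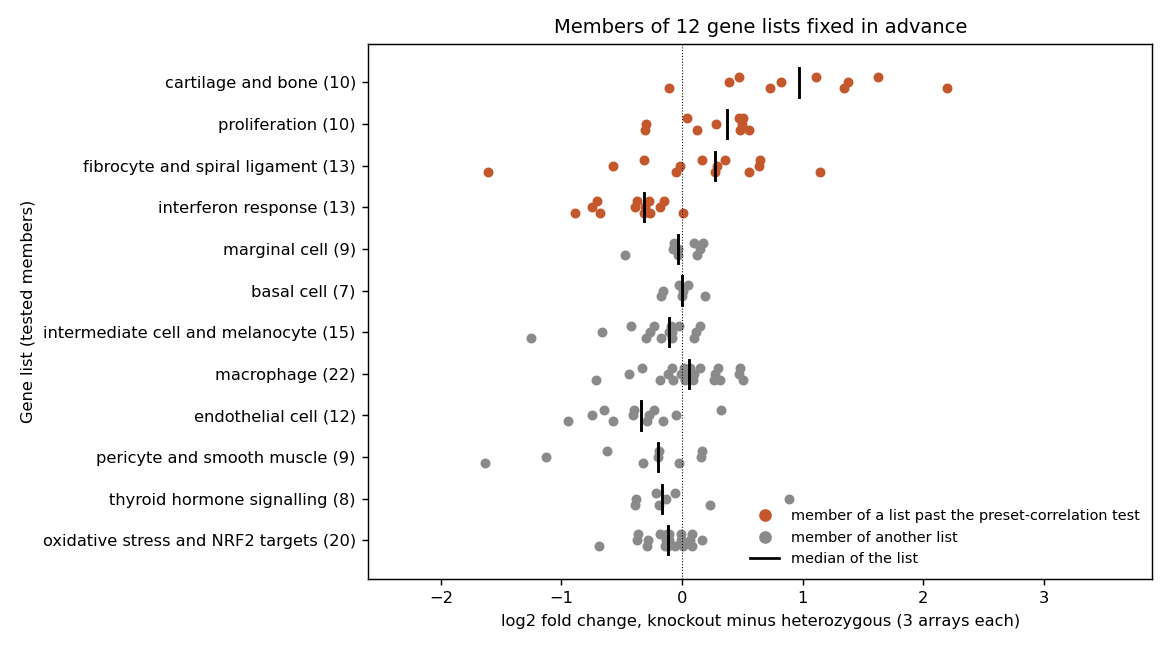
Log2 difference, knockout minus heterozygous, of each tested member of 12 gene lists, 1 point per gene, with black bars at the median and orange points for the 4 lists past the camera test with a preset correlation. The cartilage and bone list has its median at 0.97, while the marginal and basal cell lists lie close to 0.

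Another 3 of the 33 lists passed the test with the preset correlation, and none of the 4 was kept with an estimated correlation. Fibrocyte and spiral ligament genes rose (median 0.28 over 13 genes, adjusted p = 0.0166, and adjusted p = 0.812 with an estimated correlation). Col9a2 (0.56) and Col1a1 (1.15), which encode fibrillar matrix collagens or their partners, passed when adjusted over the list alone, and 5 members were lower, among them Lum at -1.61. The mean over the list was 0.12. For Col1a1 the groups overlapped, with 2441 in knockout replicate 2 and 2911 in heterozygous replicate 5. Whether the rise of this list was separate from that of the cartilage and bone list was not tested. Proliferation genes rose (median 0.38 over 10 genes, adjusted p = 0.0430, and adjusted p = 0.812 with an estimated correlation), with Rrm2, a subunit of ribonucleotide reductase, at 0.50, and no member passed when adjusted over the list alone. Interferon response genes fell (median -0.32 over 13 genes, adjusted p = 0.0207, and adjusted p = 0.812 with an estimated correlation), with 12 of 13 lower and no member past the threshold over the list alone. Oasl2 stood at -0.70, and at -0.36 without knockout replicate 2, and Ifih1 at -0.39. The interferon list did not pass without knockout replicate 2 (adjusted p = 0.369) or heterozygous replicate 3 (adjusted p = 0.398), and its adjusted p ranged from 6.7e-06 to 0.812. Its median was -0.34 without that knockout array, -0.21 without that heterozygous array and -0.57 without heterozygous replicate 1. The proliferation list was called in 10 of 20 alternatives (adjusted p from 0.00149 to 0.812), and not without heterozygous replicate 1 (0.256), knockout replicate 2 (0.551) or knockout replicate 6 (0.0570). The fibrocyte list was called in 15 of 20 (adjusted p from 7.62e-06 to 0.812), and not without heterozygous replicate 1 (0.226) or knockout replicate 6 (0.139). Its median was 0.14 without heterozygous replicate 1 and 0.13 with array weights.

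Among the lists that did not pass, 6 members of 6 lists besides the strial cell types passed when adjusted over the list alone. Dio2, the deiodinase that makes active thyroid hormone, stood at 3194 ± 551 in heterozygous and 5900 ± 933 in knockout samples (SD, n = 3 each), a log2 difference of 0.89 (adjusted p = 0.00139 over the list alone and 0.213 over all probe sets). The thyroid hormone list had a median of -0.16 with Thra, a thyroid hormone receptor, at -0.38. Acta2, the smooth muscle actin, had -1.63 in the pericyte list, Ccn1, a secreted matricellular protein, 0.97 in the immediate early list, and Atp2b4, a plasma membrane calcium pump, 1.02 in the calcium transport list. Pfkp, a phosphofructokinase, had -0.48 in the glycolysis list, but its other probe set gave 0.74 and the mean of its probe sets 0.13, so its direction was not settled. Ncmap, a myelin protein, had 0.82 in the Schwann cell list. Over all probe sets the limma adjusted p was 0.351 for Acta2 and 0.370 for Ccn1, Atp2b4, Pfkp and Ncmap. With no adjustment across the 33 lists, some members can pass by chance.

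Immune and vascular cell markers went both ways and moved with knockout replicate 4. Macrophage genes had a median of 0.06 over 22 genes and did not pass (adjusted p = 0.327). Without knockout replicate 4 their median was 0.31 and the list passed with the preset correlation (adjusted p = 1.97e-06) but not with an estimated one (adjusted p = 0.749). Cd68, a macrophage marker, stood at 171 ± 17.0 in heterozygous and 244 ± 30.5 in knockout samples (SD, n = 3 each), a log2 difference of 0.48 that did not pass (limma adjusted p = 0.423). Lgals3, another member of that list, differed by -0.71 (limma adjusted p = 0.437), and by -1.02 to -0.43 over the alternatives. Without that array the complement and neuron lists passed as well (adjusted p = 0.0201 and 0.00149), and neither was kept with an estimated correlation (adjusted p = 0.649 and 0.513). Endothelial genes had a median of -0.34, and 0.09 without that array, in which their median deviation from the heterozygous mean was -1.16. Pericyte and smooth muscle genes had -0.20, antigen presentation genes -0.25, with H2-Aa at -1.09 and Cd74 at -0.84, and granulocyte genes -0.71. Without knockout replicate 4 these medians were 0.06 for pericyte, -0.03 for antigen presentation and -0.05 for granulocyte genes. The antigen presentation list passed in 6 of 20 alternatives (adjusted p from 0.00515 to 0.812), among them without heterozygous replicate 1 and without knockout replicate 6, each with a lower median (-0.33 and -0.34). The endothelial list passed without heterozygous replicate 5 (adjusted p = 0.0309) and without knockout replicate 6 (0.00458), and the pericyte list without heterozygous replicate 5 (0.0406) and with the mean of a gene's probe sets (0.0422), where their adjusted p ranged up to 0.883 and 0.812. The granulocyte list passed with no filter (0.0149, range up to 0.883) and the erythrocyte list with array weights (0.0148, range up to 0.812). The medians were -0.24 for lymphocyte, -0.54 for erythrocyte, -0.46 for neuron and -0.41 for hair cell genes, all on 3 or 4 genes. These moved with single arrays, to -0.06 for lymphocyte genes without heterozygous replicate 3, -0.10 for erythrocyte genes without knockout replicate 2 and -0.01 for hair cell genes without heterozygous replicate 5. The neuron list ranged from -0.70 to -0.31 and passed in 4 of 19 alternatives, and the macrophage median ranged from -0.08 (without knockout replicate 2) to 0.31 and that list passed in 2 of 20. The Schwann cell list had -0.06.

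The lists on ion, acid-base and stress functions did not pass. Median log2 differences were -0.01 for acid-base transport and carbonic anhydrases, 0.13 for calcium transport, 0.08 for chloride and other strial channels, -0.02 for tight junctions and -0.11 for oxidative stress. Car2, a carbonic anhydrase, gave 0.04 ± 0.08 (SE), and Hmox1, the haem oxygenase, -0.69 ± 0.47. The Hmox1 signal was 198 in knockout replicate 4 and at least 816 in every other sample, and without that array its log2 difference was 0.0055. Trpv6, a calcium channel, lay under the signal filter in these samples, and Trpv5 had no probe set in the annotation. The skeletal muscle list had 0 tested members. Medians of 0.19 for complement, 0.08 for cytokines and chemokines, -0.04 for lysosome, -0.21 for the unfolded protein response and -0.06 for immediate early genes did not pass either. The same held for glycolysis at -0.13, oxidative phosphorylation at 6.5e-05, extracellular matrix at -0.07 and melanin and metal handling at -0.04. Without knockout replicate 4 the median was 0.01 for the unfolded protein response, -0.02 for oxidative stress, -0.06 for thyroid hormone and 0.07 for calcium transport. Without that array it was -0.07 for glycolysis, 0.03 for chloride and other strial channels and 0.29 for complement. It was 0.07 for immediate early genes and 0.06 for extracellular matrix, which also turned in sign, as did basal cells, Schwann cells, acid-base transport, lysosome, oxidative phosphorylation, and melanin and metal handling, all within 0.03 of 0. Under other alternatives the sign also turned for calcium transport (-0.15 with the 60th percentile filter), cytokines (-0.12 without knockout replicate 2 and 0.31 without heterozygous replicate 3), complement (-0.07 without knockout replicate 2), tight junctions (0.03 at most) and chloride channels (lowest -0.0045). Where a list's median or mean and its camera direction differed in sign, as for marginal, basal and Schwann cells, acid-base transport, chloride channels, tight junctions, lysosome, immediate early genes, oxidative phosphorylation, and melanin and metal handling, the list did not pass.

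Genes beside Slc26a4 were examined because a targeted allele can carry flanking sequence of another strain. Within 10 Mb on its chromosome, 2 of 54 tested genes had an unadjusted p under 0.01 (Meox2 and Rrm2), against 166 of 12325 elsewhere. The odds ratio was 2.82, with p = 0.166 in a two-sided Fisher exact test, and no neighbour was called. Only 1 gene was called anywhere, so the lack of a called neighbour decides nothing. The 2 neighbours are too few for the test to exclude an effect of flanking sequence.

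Sex-linked genes set knockout replicate 6 apart from the other samples. Xist, which is transcribed from the inactive X chromosome, gave a signal of 4919 in knockout replicate 6 and at most 83.1 in the others. The Y-linked gene Eif2s3y gave at least 2835 in the other 5 samples and 6.98 in knockout replicate 6. Read from these genes, knockout replicate 6 was female and the other 5 samples male, though the labels give no sex. Sex was thus not balanced between the genotypes. Read this way, leaving out knockout replicate 6 compared male samples only. That setting gave a log2 difference of -1.92 for Slc26a4 and called 0 probe sets. Fgf18 stood at 275 and 249 in knockout replicates 2 and 4, against 38.9 to 46.7 in heterozygous samples. The setting also removed 1 of 3 knockout samples, so an effect of sex was not separated from that of a smaller group.

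**Figure D3:**
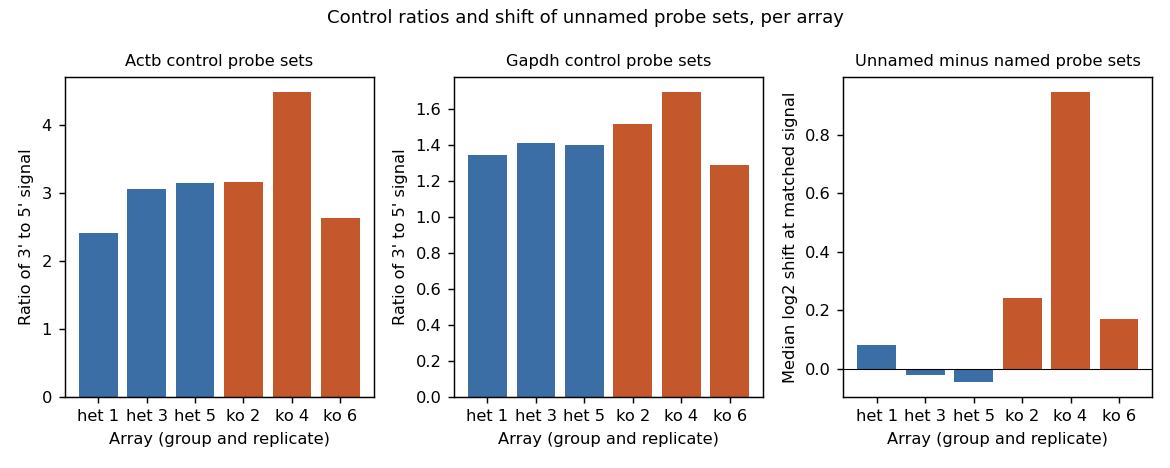
Ratio of 3' to 5' signal of the Actb and Gapdh control probe sets, and the median log2 shift of unnamed against named probe sets of the same signal, with 1 bar per array, heterozygous (het) in blue and knockout (ko) in orange. Knockout replicate 4 has the highest bar in each panel, with an Actb ratio of 4.48 where the others reach at most 3.15.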

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

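All tests in this part, and the bound of 3 SD, were chosen after the values were seen. Control probe sets that entered no comparison were compared with the heterozygous arrays, and a knockout array was listed where it lay above each of them and above their mean by more than 3 SD. Knockout replicate 4 had an Actb 3' to 5' ratio of 4.48 (heterozygous mean 2.87 ± 0.396 SD, n = 3), a Gapdh ratio of 1.69 (1.39 ± 0.0338) and a mean signal of the hybridisation spikes of 3228 (2142 ± 14.8). Knockout replicate 2 had a Gapdh ratio of 1.52 and a spike signal of 2238. The rule looked at knockout arrays and at high values only. Knockout replicate 6 lay below the lowest heterozygous array, with a Gapdh ratio of 1.29 (lowest 1.35) and a spike signal of 2100 (lowest 2128). Between the genotypes, exact permutation tests gave p = 0.4 for the Actb ratio, 0.5 for the Gapdh ratio and 0.4 for the spikes. With 3 samples per group, single values inside a group were not tested as outliers.

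Knockout replicate 4 was the array farthest from the rest, with correlations of 0.916 to 0.950 to the others, where all other pairs reached at least 0.970, and the first principal component, at 59.6% of the variance, placed it alone at 89.9. A mislabelled heterozygous sample is argued against: over the 100 probe sets that best separated the other knockout arrays from the heterozygous ones, it lay at a mean position of 0.950 ± 0.688 (SD over probe sets) on a scale from heterozygous (0) to knockout (1), with 95 of 100 on the knockout side, and Slc26a4 lay at 1.02. Lower RNA quality or less efficient amplification stays open: its Gapdh ratio lay 3.56 SD and its Actb ratio 4.76 SD above the other 5 arrays, but these are the values that set the array apart above, so they are no separate test of it. A smaller share of endothelial cells stays open: the median of those markers relative to the other 5 arrays was -1.24 on the log2 scale, which is -0.64 from the lowest of 4 compared cell types and past the bound of 0.5 set for this explanation, but it also required that no compared list be lowest in this array, and macrophage (-0.61) and intermediate cell (-0.20) markers were, as were granulocyte markers (-2.27); the size alone was at first read as in favour, before that condition was applied. No group of the design sets this array apart, no biological explanation other than the endothelial share was tested, and RNA quality and cell content were not separated.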

How the results depend on the processing

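No paired analysis was possible because the groups share no replicate number. The alternatives of 1 probe set per gene and of named probe sets only were chosen after seeing the data. The direction of Slc26a4 was kept in all 17 alternatives, with a log2 difference from -2.23 to -1.02 and no call in any. The count of probe sets called, 1 in the reported setting, was 4 with a floor of 32, 3 with quantile and 2 with cyclic loess normalisation, 25 with array weights, 5 at an adjusted p under 0.1 and 5 over named probe sets only. It was 0 with no filter and 0 with a 60th percentile filter, which removes Fgf18. An unmoderated test at an unadjusted p under 0.05 gave 251 with at least a 2-fold change and 1646 without that bound, and 0 after Benjamini-Hochberg adjustment. Leaving out 1 array gave 0 to 13, with 13 without knockout replicate 4, 3 without heterozygous replicate 3, 2 without heterozygous replicate 1 and 0 without any of the other 3. The count of genes, also 1, was 4 with the floor, 3 with quantile and 2 with cyclic loess normalisation, 0 with no filter and 0 with the 60th percentile filter, 18 with array weights, 3 for the mean of a gene's probe sets and 11 with 1 probe set per gene in the fit. Leaving out 1 array gave 0 to 10 genes, with 10 without knockout replicate 4, 3 without heterozygous replicate 3 and 0 otherwise. Of the lists, 4 as reported, 8 were called with array weights, 0 with an estimated correlation, 0 with the directional and 1 with the mixed fry test, and 2 to 7 when leaving out 1 array, with 2 without knockout replicate 2 and 7 without knockout replicate 4. The odds ratio of the neighbours of Slc26a4 was 0 in a window of 5 Mb (Fisher exact p = 1). Apart from the 60th percentile filter, the cause was not tested. Robust variance gave no list result, since camera has no such option. For single genes, 28 values passed the threshold only under an alternative and 6 lost it, and no called value changed sign. For lists, 23 values passed only under an alternative and 23 lost the threshold. The signal at the filter was about 43.9, and 35.4% of probe sets on a typical array lay under a signal of 32, so changes of dim genes are limited by background.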

Other observations

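Of the tests in this part, the bone genes outside the list, the receptor probe sets and the splits of the samples were chosen before their results were seen, and the others after.

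Bone genes that were not in the fixed list moved in part with it. Of 16 tested genes of osteoblasts, osteocytes and osteoclasts, 14 were higher in knockout samples. Panx3, a channel of osteoblasts and hypertrophic chondrocytes, had a log2 difference of 1.93 (unadjusted p = 0.000939), with knockout signals of 280, 578 and 430 against 44.1, 107 and 176. Omd, a keratan sulphate proteoglycan of bone, had 1.35, and Col22a1 1.21. Kcnk2 was the member farthest on the other side, at -1.29. The 5 osteoclast genes Nfatc1, Itgb3, Tcirg1, Clcn7 and Ostm1 lay between -0.05 and 0.15. By contrast, the osteoclast enzymes in the fixed list, Mmp9 (2.19), Acp5 and Ctsk, were higher. The osteoblast and osteocyte genes ranged from -1.29 for Kcnk2 to 1.93 for Panx3.

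The cartilage and bone list was weighed against 3 explanations. Knockout replicate 4 alone is argued against, since the list's median was 1.06 without that array and 0.97 with it. A general shift of named genes of that signal is argued against, since 10000 random lists of them had a typical median of -0.0295 and none reached 0.97. These lists held named genes only, so they cannot test the shift of unnamed probe sets. Their genes were drawn singly, so the lists do not carry any joint variation of bone genes. Bone tissue carried over at dissection, or more bone cells in the tissue, may contribute. The genes outside the list had a camera p of 6.07e-06 with the preset correlation but 0.0824 with an estimated one. Their median was 0.22, with a bootstrap interval over genes of 0.12 to 0.56, which leaves out the spread between arrays. That median lay between the bounds set beforehand. The bounds were set for osteoblast, osteocyte and osteoclast genes together, and these classes were not tested apart. Dissection, a change of the tissue with genotype and a change within its cells thus cannot be told apart here.

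Probe sets without a gene name were higher in knockout samples, with 1221 of 3530 tested above at an unadjusted p under 0.05 and 53 below, against 1219 and 608 of 22886 named ones. Scaling that lifts all dim probe sets alike is argued against. On the log2 scale the unnamed ones lay 0.45 above named ones of the same signal (exact permutation p = 0.1, the smallest possible). The difference was 0.95 in knockout replicate 4, 0.24 and 0.17 in the other knockout arrays, and -0.05 to 0.08 in heterozygous ones. Each array was set against the heterozygous mean, which holds heterozygous values near 0. The permutation test was run on a pattern seen in the same data. For genomic DNA or general background, the change of 86 olfactory, vomeronasal and taste receptor probe sets was set against that of unnamed ones of the same signal. The ratio was -0.0255 (95% bootstrap interval over probe sets, not arrays, -0.41 to 0.43), which met the bound set beforehand for excluding this explanation. That bound was set aside after the result was seen, because 0 of the 86 passed the signal filter and probe sets near the floor exclude nothing, so the explanation stays open. Loss of RNA quality may contribute and stays open beside genotype itself, which was not tested, since against the Actb 3' to 5' ratio over 6 arrays the shift had Spearman rho 0.49 (permutation p = 0.356) and Pearson r 0.85 (permutation p = 0.103), neither past 0.05, and r was -0.30 without the 2 farthest arrays, while for the Gapdh ratio rho was 0.49 (permutation p = 0.356) and r 0.84 (permutation p = 0.0639), and 0.68 without the 2 farthest, and among 3 such relations, 18S ribosomal RNA included, the lowest permutation p was 0.0333, and 0.0958 after Benjamini-Hochberg adjustment.

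The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The genotype split called 1 probe set and 1 gene, and the highest of the other splits called 0 of each, so 1 of 10 splits gave as many for either count. It called 4 gene lists with the preset correlation, the highest other split called 8, and 7 of 10 splits gave at least as many. The split with 8 lists set heterozygous replicates 1 and 3 with knockout replicate 4.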
